A study of Mus musculus with 8 samples.

How the data were processed

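RNA from mouse pancreatic islets was profiled in 8 libraries, 2 from each of 4 groups. Mice were of the C57BL/6 strain and were either wild type or carried a deletion of Tcf7, the gene of the transcription factor TCF-1. Islets came from animals aged 8 weeks on a diet with 10% fat or from animals aged 20 weeks on a diet with 45% fat. Diet and age therefore changed together, and no comparison could separate them. The treatment field of the labels speaks of regular chow where the diet field gives a low-fat diet, and the age at which the diets began is missing from the design text. Ribosomal RNA was depleted and libraries were made with an Illumina TruSeq kit, per the labels' protocols. Whether the kit kept strand is not given in the sources used here.

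The submitters' processing notes name CASAVA 1.8, FastQC, TopHat 1.4.1 and the mouse build mm9. The counting tool, the gene annotation and the use of strand in counting are not given in the sources used here. The deposited table gave values in RPM, reads scaled by the library total, for 22632 genes, as made by the authors. Values in a library were whole multiples of the value of 1 read: 100% of them came out whole within 0.01 of a read. The recovered library totals were 58.7 to 191 M reads, and the listed genes took 41.6% to 61.2% of each total. The authors' denominator was thus larger than the reads in listed genes. Reads in listed genes numbered 32.7 to 103 M per library, so that 1 read was worth 0.00523 to 0.0170 RPM.

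Fold changes were computed on log2(RPM + 1), which understates the change of genes with low values. Genes with at least 1 RPM in at least 2 libraries were tested, 13347 in all. limma 3.58.1 in R 4.3.3 fitted the means of the 4 groups together, with a mean-variance trend, 4 residual degrees of freedom and 14.0 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The contrasts were knockout against wild type at each setting, their mean, their difference (the interaction), and 20 weeks against 8 weeks in each genotype and on average. Errors of fold changes are standard errors from limma, and errors of RPM are SD over n = 2 libraries. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these samples. Replicate libraries differed by far more than sampling noise, with a chi-square per degree of freedom of 42.9 to 339, and none was merged. As the unit was RPM, limma was the main test, and edgeR 4.0.16 (quasi-likelihood test with TMM scaling) on the recovered reads was added as an alternative after the values were seen.

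Gene lists of islet cell types, other cell types, signalling, stress and metabolism were fixed before the data were examined, 25 in all, beside a check list of sex-linked genes. The 24 lists with at least 2 tested genes were compared with all other genes by camera, with a preset correlation of 0.01, and again with the correlation estimated from the data. The Y-linked genes of the check list were present in all 8 libraries, with Ddx3y between 56.5 and 85.2 RPM. Genes were named by a rule fixed before the data were examined: Tcf7, the 8 highest and 8 lowest fold changes among called genes whose groups did not overlap, up to 3 members of each list with a call, the 10 smallest p-values where fewer than 10 genes passed or for the mean and interaction contrasts, and 13 genes of islet biology. Other called genes named below were chosen after their values were seen. Unnamed clones were in part left out, and some genes that the rule names are not reported here.

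Alternatives planned beforehand were median-of-ratios scaling, no filter, a minimum of 5 RPM, a pseudocount of 0.1, no mean-variance trend, a fit of the compared libraries alone, a threshold of 0.10, the mean of the acinar list as a covariate, an estimated correlation for the lists, and leaving out each library in turn. Gene overlaps and intron shares were taken from GENCODE M21 on the build GRCm38, which is not the build of the authors' alignment, so no coordinates are given. Of the 22632 identifiers, 20750 (91.7%) matched. Of the symbols deposited, 25 had been turned into dates and were restored by identifier, and of 135 repeated symbols the row with the highest mean kept the symbol. On simulated data for the 8-week genotype contrast over 13347 genes, limma recovered 66 of 100 genes changed 2-fold and 94 of 100 changed 4-fold, with 98 of each 100 passing the filter and 14 false calls. A simulated 1.5-fold change of the cholesterol list was found by camera with an adjusted p of 7.8e-32, and 0 other lists were called. Genes were drawn independently of each other in this simulation. It therefore does not test how specific camera with the preset correlation is where genes vary together. Annotation and figures were handled in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.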

Results

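Total RNA of mouse islets, the hormone-producing cell clusters of the pancreas, was sequenced in 4 groups of 2 libraries each. The groups were wild type and Tcf7 knockout at 8 weeks on 10% fat, and wild type and Tcf7 knockout at 20 weeks on 45% fat. Total depth was 112 and 155 M reads in the wild-type libraries at 8 weeks and 191 and 164 M in the knockout-labelled libraries. At 20 weeks it was 169 and 67.6 M in the wild-type libraries and 58.7 and 69.4 M in the knockout-labelled libraries. Listed genes held 41.6% to 51.0% of the reads at 8 weeks and 55.7% to 61.2% at 20 weeks. The first principal component held 75.4% of the variance and separated the 8-week from the 20-week libraries.

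Tcf7 (ENSMUSG00000000782), the targeted gene, was not lower in the libraries labelled knockout. At 8 weeks it stood at 0.329 ± 0.0733 RPM (SD, n = 2) in wild type and 0.515 ± 0.00449 RPM in knockout-labelled libraries, with 31 and 59 reads against 98 and 85 reads. At 20 weeks it stood at 1.28 ± 0.416 RPM in wild type and 3.56 ± 1.41 RPM in knockout-labelled libraries. The log2 fold change was 0.19 ± 0.22 at 8 weeks (limma adjusted p = 1) and 0.97 ± 0.22 at 20 weeks (limma adjusted p = 0.16). The deleted part of the gene is not stated in the labels, and a count over the whole gene does not check it. Every direction below therefore rests on the labels alone, which the Tcf7 values neither bear out nor refute. Lef1, a related factor, stood at 3.67 and 2.37 RPM in wild type at 20 weeks and 11.4 and 4.86 RPM in knockout-labelled libraries, with a log2 fold change of 1.10 ± 0.27 that did not pass (limma adjusted p = 0.23). Tcf7 and Lef1 were left out of a fit, given below, without genes that overlap an opposite-strand gene. The reason was an overlap with a gene that has no deposited values or the want of a match in the reference. Reads of an opposite-strand gene in their 20-week values were thus not excluded.

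**Figure D1:**
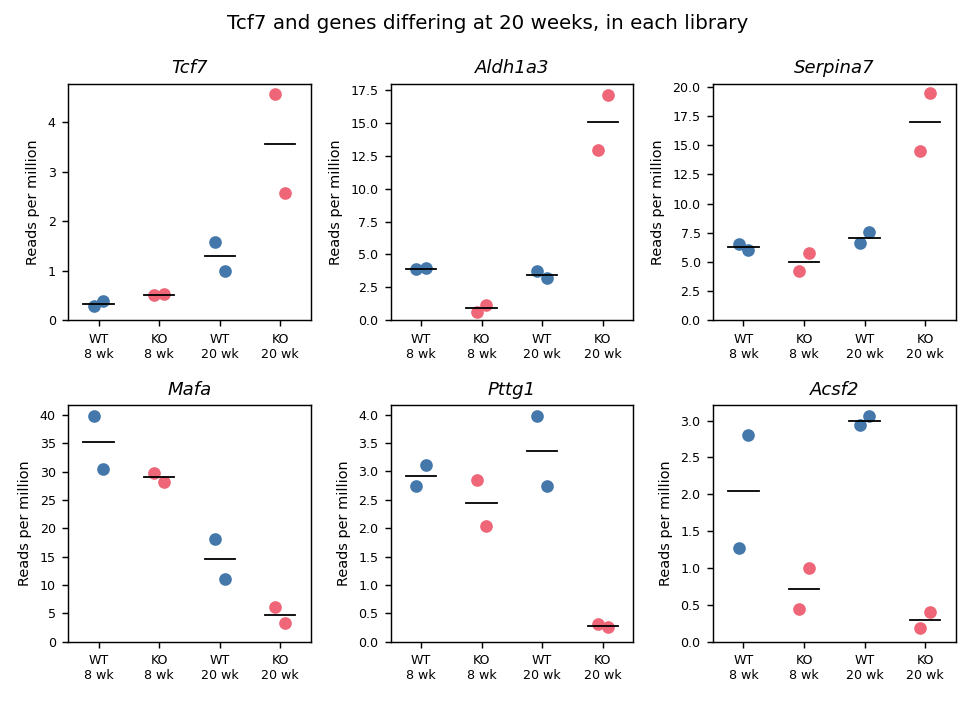
RPM of Tcf7 and 5 other genes (y axes, linear) in each of the 8 libraries, by group on the x axes (WT wild type, KO labelled knockout, wk weeks). Points are libraries and black lines are group means; Aldh1a3 stood at 12.9 and 17.2 RPM in the knockout-labelled libraries at 20 weeks and at 0.606 and 1.18 RPM in those at 8 weeks.

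The first comparison set islets labelled knockout against wild type in 8-week animals on low fat. Bank1, Ptprc and further genes known from leukocytes were among 26 genes called lower in the knockout-labelled libraries, though no leukocyte list passed with an estimated correlation. Bank1, a B cell scaffold protein, stood at 9.64 and 4.55 RPM in the wild-type libraries and 0.105 and 0.110 RPM in the knockout-labelled ones (log2 fold change -2.79 ± 0.24, limma adjusted p = 1.3e-05). Ptprc, which encodes the common leukocyte antigen CD45, fell from 10.2 ± 1.55 to 1.73 ± 0.192 RPM (SD, n = 2; log2 fold change -2.04 ± 0.22). Aldh1a3, a retinaldehyde dehydrogenase, fell from 3.90 ± 0.0528 to 0.892 ± 0.404 RPM (log2 fold change -1.39 ± 0.21, limma adjusted p = 0.0046). In all, 26 genes were lower and 2 higher among 13347 tested by limma, and edgeR on the recovered reads called 23 lower and 1 higher, of which 13 were shared.

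Further calls among leukocyte genes were Arhgap15 (-2.09), Dock2 (-1.92), the myeloid lysozyme Lyz2 (-1.82), Wdfy4 (-1.78), the lymphoid factor Ikzf1 (-1.76) and the B cell factor Pax5 (-1.71), all as log2 fold changes. Dock2 and Wdfy4 overlap genes on the other strand. Arhgap15, Bank1, Ikzf1, Pax5 and Ms4a1 were also left out of the fit without overlapping genes. The reason was an overlap with a gene without deposited values or the want of a match. Of 5 tested genes of the T and B lymphocyte list, 3 fell over all genes tested and 4 adjusted over the list alone, with a median log2 fold change of -1.11. They included Ms4a1, the B cell antigen CD20 (-1.43), and Cd79b, a part of the B cell receptor (-1.11). The list was lower by camera with an adjusted p of 1.7e-23, but an adjusted p = 0.055 with an estimated correlation. Of 12 macrophage and antigen presentation genes 1 fell (3 adjusted over the list alone), with Cd74 at -0.81 and H2-Ab1 at -0.63 not passing over all genes. Of 11 fibroblast, stellate and mural genes 1 fell, Thy1 (-0.998), and 2 adjusted over the list alone, while Dcn (-1.18) and Col3a1 (-0.54) did not pass over all genes. The camera adjusted p of these lists was 3.9e-05 and 4.4e-04, against an adjusted p of 0.59 and 0.83 with an estimated correlation. Chosen after their values were seen, genes of peripheral neurons were also among the calls, with Prph at -1.57, Nos1 at -1.57, Sncg at -1.24 and Nefl at -1.15, as was the globin gene Hba-a2 at -1.41.

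**Figure D2:**
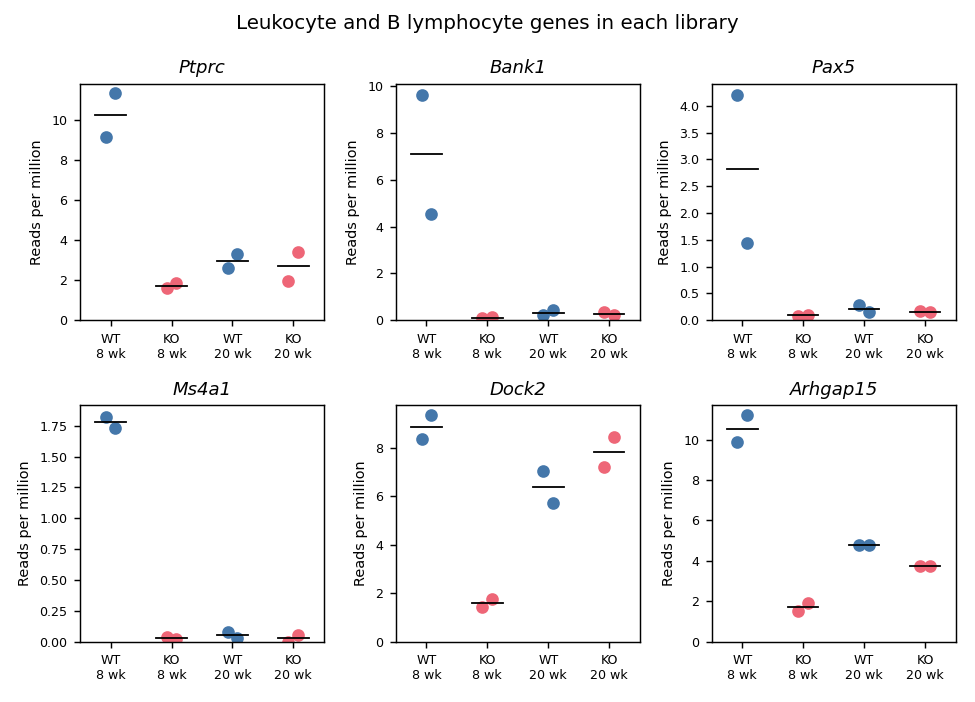
RPM (y axes, linear) of 6 genes of leukocytes in each library, by group on the x axes (WT wild type, KO labelled knockout, wk weeks). Points are libraries and black lines are group means; Ptprc was 9.15 and 11.3 RPM in wild type and 1.59 and 1.86 RPM in knockout-labelled libraries at 8 weeks.

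Of genes of the exocrine pancreas 1 was called. The pancreatic amylase Amy2a5 rose from 7.09 ± 4.99 to 30.7 ± 11.6 RPM (SD, n = 2; log2 fold change 2.07 ± 0.41, limma adjusted p = 0.043), and the fucosyltransferase Fut2 rose by 0.98 on the log2 scale. Amy2a5 belongs to a family of near-identical copies, so its reads are uncertain. Without knockout replicate 1 Amy2a5 (1.69) and Fut2 (0.83) lost their call, as did Fut2 without wild-type replicate 2 (0.92). All 28 tested acinar genes had positive fold changes, with a median of 1.82; 1 rose over all genes tested and 26 adjusted over the list alone. Clps (2.10) and Pnliprp2 (1.76) did not pass over all genes. The mean log2 value of the acinar list was 5.83 and 7.18 in wild type and 8.67 and 7.77 in knockout-labelled libraries. All 9 duct genes were positive too, 2 adjusted over the list alone, with Krt19 at 1.53, Muc1 at 0.92 and Cftr at 0.46 not passing over all genes. The camera adjusted p was 9.2e-73 for acinar and 5.8e-09 for duct genes, against an adjusted p of 0.2 and 0.25 with an estimated correlation. Lists of p53 targets, immediate early genes and ribosomal proteins had small positive medians of 0.12, 0.19 and 0.12 and no called member. Their camera adjusted p was 0.0027, 0.012 and 0.0022, and no list passed with an estimated correlation (adjusted p of 0.84, 0.95 and 0.83 for these). Examples were Trp53inp1 (0.60), Perp (0.44), Eda2r (0.34), Klf4 (0.37), Junb (0.37), Ier2 (0.32), Rpl32 (0.27), Rpl13 (0.24) and Rps14 (0.21), none of which passed.

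No gene of the beta cell list was called at 8 weeks by limma, and Aldh1a3 was the 1 called of 13 disallowed and dedifferentiation genes. Log2 fold changes were -0.05 for Ins1, -0.11 for Ins2, -0.24 for Pdx1, -0.26 for Mafa, 0.28 for the incretin receptor gene Gipr and 0.02 for Glp1r. They were 0.29 for glucagon (Gcg), 0.02 for Tcf7l2, -0.26 for Lef1, 0.23 for Axin2, 0.14 for Cdkn1a, 0.09 for Trp53, -0.29 for Mki67, 0.27 for Myc and -0.29 for Serpina7, each with a limma adjusted p of 1. With median-of-ratios scaling 9 genes remained, all lower and all among the 28, and with the acinar list mean as covariate 9 were called, 6 of them among the 28. The direction of the calls depended on the filter and on single libraries, with 49 higher and 14 lower at a minimum of 5 RPM. Without knockout replicate 1, the library with the highest acinar mean of its age, 7 genes were higher and 9 lower, and 9 of the 28 kept their call. Without wild-type replicate 2, 113 were higher and 60 lower, without wild-type replicate 1, 34 and 44, and without knockout replicate 2, 44 and 180. Leaving out a 20-week library, which bears only on the estimate of spread, gave 45 and 39 or 50 and 40 without wild-type replicate 1 or 2, and 8 and 40 without each knockout replicate.

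The second comparison asked the same at 20 weeks on high fat. Aldh1a3 was higher here, at 12.9 and 17.2 RPM in the knockout-labelled libraries against 3.72 and 3.20 RPM in wild type (log2 fold change 1.84 ± 0.21, limma adjusted p = 6.8e-04). Pttg1, which encodes the mitotic inhibitor securin, was lower, at 0.283 ± 0.0333 against 3.36 ± 0.875 RPM (SD, n = 2; log2 fold change -1.75 ± 0.21, limma adjusted p = 6.8e-04). Acsf2, an acyl-CoA synthetase gene that overlaps a gene on the other strand, was lower (log2 fold change -1.63), and Wdr95 was higher (3.08). Wdr95 had 11 and 6 reads in wild type and 0 and 8 reads in knockout-labelled libraries at 8 weeks. At 20 weeks it had 645 and 70 against 2748 and 943 reads. The fit without overlapping genes left it out, for an overlap with a gene without deposited values or for want of a match. Mafa, a transcription factor of mature beta cells, stood at 6.20 and 3.30 RPM against 18.1 and 11.1 RPM, with a log2 fold change of -1.45 ± 0.26 that missed the threshold (limma adjusted p = 0.052). Serpina7, the thyroxine-binding globulin, stood at 14.5 and 19.5 RPM against 6.64 and 7.52 RPM (1.15 ± 0.21, limma adjusted p = 0.059).

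In all, 4 genes rose and 2 fell among 13347 tested by limma, the other rises being the clones 1700001K19Rik (1.49) and CN725425 (1.06). The clone 1700001K19Rik was left out of the fit without overlapping genes too. Nmnat2 (-1.21, limma adjusted p = 0.054) and Stra6 (1.002, limma adjusted p = 0.052), which overlaps Ccdc33 on the other strand, were the next smallest p-values along with Mafa and Serpina7. At an unadjusted p under 0.05 limma had 582 genes. edgeR on the recovered reads called 0 genes, with 1414 at an unadjusted p under 0.05, and gave Aldh1a3 an adjusted p of 0.06. With median-of-ratios scaling 1 gene was called, Aldh1a3, so the share of higher calls moved from 66.7% to 100%.

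Of 13 disallowed and dedifferentiation genes, which islet cells normally keep low, 1 rose, Aldh1a3, and 2 adjusted over the list alone (median 0.19). By camera the list had an adjusted p of 3.1e-05, against an adjusted p of 0.85 with an estimated correlation. No member of the other lists was called over all genes. The acinar list had a median of -0.82 (camera adjusted p = 5.0e-11, and 0.85 with an estimated correlation), with Cuzd1 at -1.43, Pnliprp2 at -0.99 and Amy2a5 at -0.94. The highest acinar mean was that of wild-type replicate 2, at 9.05 against 7.42 in replicate 1 and 7.37 and 7.59 in the knockout-labelled libraries. Positive medians stood at 0.19 for ribosomal proteins (Rpl13 0.60, Rpl37 0.52), 0.14 for immediate early genes (Hspa1a 0.80, Hspa1b 0.74, Cyr61 0.75) and 0.14 for metallothionein and oxidative defence genes (Slc7a11 0.82, Mt1 0.56, Mt2 0.54). They stood at 0.29 for delta, PP and epsilon genes (Ppy 0.77, Ghsr 0.36, Ghrl 0.29) and 0.39 for duct genes (Cftr 0.62, Krt19 0.74, Sox9 0.45), and at -0.20 for cholesterol synthesis. The camera adjusted p of these 6 lists ran from 2.1e-06 to 0.0039, and each had an adjusted p of 0.85 with an estimated correlation. Log2 fold changes of 0.36 for Ins1, 0.37 for Ins2, -0.36 for Pdx1, -0.39 for Glp1r, -0.20 for Gipr, -0.11 for Gcg, -0.10 for Tcf7l2, -0.43 for Axin2, 0.01 for Cdkn1a, -0.06 for Trp53 and -0.20 for Mki67 had a limma adjusted p of 1. A fit of these 4 libraries alone called 266 genes, and leaving out 1 library at a time gave 15 to 86 genes, with more higher than lower each time. Of this age, 15 were higher and 14 lower without wild-type replicate 1, 14 and 5 without wild-type replicate 2, 17 and 4 without knockout replicate 1 and 35 and 5 without knockout replicate 2. Leaving out an 8-week library gave 69 and 17 without each wild-type and 8 and 7 without each knockout replicate. Aldh1a3, Pttg1, Acsf2 and Wdr95 kept their call without each library, whereas CN725425 lost it without wild-type replicate 2 of this age and 1700001K19Rik without that library or knockout replicate 1.

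The mean and the difference of the genotype contrasts were tested next, and a call in the mean need not hold at each setting. Bank1, Arhgap15, Ptprc, Dock2 and Ms4a1 were called in both, and Bank1 stood at 0.207 and 0.429 RPM in wild type and 0.341 and 0.202 RPM in knockout-labelled libraries at 20 weeks. Averaged over settings, limma called 12 genes lower and 2 higher, but with a minimum of 5 RPM 9 and 12, without wild-type replicate 1 or 2 of 8 weeks 34 and 47 or 37 and 94, and without wild-type or knockout replicate 1 of 20 weeks 13 and 19 or 12 and 26. The smallest p-values were those of Arhgap15 (-1.18 ± 0.14), Bank1 (-1.42 ± 0.17), Acsf2 (-1.21 ± 0.17), Ptprc (-1.09 ± 0.16) and Ikzf1 (-1.13 ± 0.17), followed by Pttg1 (-0.97 ± 0.15), Wdfy4 (-0.99 ± 0.15), Ms4a1 (-0.73 ± 0.12), Dock2 (-0.83 ± 0.14) and Nmnat2 (-0.90 ± 0.16), as log2 fold changes. edgeR called 2 genes lower, Arhgap15 and Dock2, and with median-of-ratios scaling 2 were lower and 0 higher, which moved the share of higher calls from 14.3% to 0%. The camera test called 13 lists for the mean and 0 with an estimated correlation. The interaction was called for 9 genes by limma, 8 of them positive, meaning a difference between genotypes that was higher at 20 weeks. Aldh1a3 had the smallest p (difference of log2 fold changes 3.23 ± 0.30, limma adjusted p = 4.3e-05) and was the 1 gene called for genotype at both settings, with opposite signs. It kept this call under each of 17 alternatives, while the prevailing sign of interaction calls turned with a minimum of 5 RPM (18 positive and 42 negative), without wild-type replicate 2 of 8 weeks (59 and 80) and without wild-type replicate 1 of 20 weeks (20 and 53). Bank1 (2.75 ± 0.34), Dock2 (2.18 ± 0.29), Arhgap15 (1.81 ± 0.27), Ptprc (1.91 ± 0.31) and Ms4a1 (1.39 ± 0.25) followed the lower leukocyte values at 8 weeks, and Nos1 stood at 2.02 ± 0.34. The values of Dock2 at 20 weeks may hold reads of Fam196b, which it overlaps on the other strand (2.90 to 6.12 RPM at that age). Bank1, Arhgap15, Ms4a1, Nos1 and Wdr95 were also left out of the fit without overlapping genes. Wdr95 stood at 3.14 ± 0.56 and Erp27, a protein of the endoplasmic reticulum of pancreas, at -3.56 ± 0.64, while Pttg1 did not pass (-1.55 ± 0.29, limma adjusted p = 0.061). edgeR called 3 of the 9, Aldh1a3, Dock2 and Arhgap15. With median-of-ratios scaling 3 of the 9 kept their call, and with the acinar list mean as covariate 1, Aldh1a3. The 2 genotype contrasts were nearly unrelated across 13347 genes, which are not independent replicates, with Pearson's r of 0.014, Spearman's rho of 0.078 and the same sign in 52.9% of genes.

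**Figure D3:**
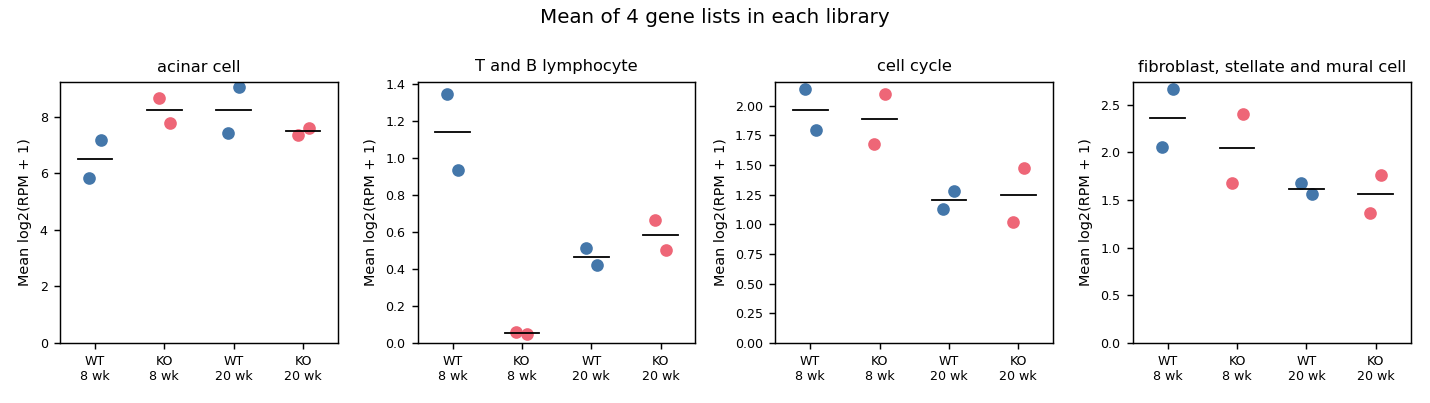
Mean of log2(RPM + 1) over the tested genes of 4 gene lists (y axes, linear) in each library, by group on the x axes (WT wild type, KO labelled knockout, wk weeks). Points are libraries and black lines are group means; the acinar mean was 8.67 in knockout replicate 1 at 8 weeks and 9.05 in wild-type replicate 2 at 20 weeks.

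The last comparison set 20 weeks on high fat against 8 weeks on low fat. Of 20 cell cycle genes 13 were called lower and 1 higher at 20 weeks, though the list had an adjusted p of 0.75 by camera with an estimated correlation. Top2a, the topoisomerase of replicating cells, had a log2 fold change of -2.11 ± 0.24, Mki67, a proliferation marker, -1.96 ± 0.25, and the centromere protein Cenpf -1.53 ± 0.22 (limma adjusted p of 1.2e-06, 8.1e-06 and 2.4e-05). Mafa fell by 1.83 on the log2 scale, from 35.2 ± 6.61 to 14.6 ± 4.90 RPM in wild type and from 29.0 ± 1.16 to 4.75 ± 2.05 RPM in knockout-labelled libraries (SD, n = 2). The neuropeptide gene Vip fell by 1.95, the matrix genes Col3a1 by 1.46 and Sparc by 1.27, and the plasma glutathione peroxidase Gpx3 by 1.24 on the log2 scale. Tcf7 was higher at 20 weeks (1.16 ± 0.16, limma adjusted p = 1.1e-05). It was among the genes left out of the fit without overlapping genes given below, so reads of an opposite-strand gene were not excluded.

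Among 13347 genes limma called 4164 higher and 807 lower at 20 weeks, on average over genotypes. The median log2 fold change of all tested genes was 0.17, and with median-of-ratios scaling, which removed that shift, 4060 were higher and 3764 lower. The share of higher calls was 83.8% as deposited, 51.9% after scaling and 49.1% by edgeR on the recovered reads, which called 3842 higher and 3988 lower. In wild type alone 2259 were higher and 217 lower, and in knockout-labelled libraries 2637 and 296 (after scaling 2787 and 2303, and 3367 and 2648). Of these, 1926 genes were called in both genotypes and 1922 with the same sign. Counts of list members below are as deposited, followed by those after scaling and, past the semicolon, those after scaling without genes that overlap an opposite-strand gene.

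The largest rises were those of Slco1a5 (10.86), Ccdc107 (8.13), AF085738 (7.82), Lrrc4 (7.33), Tnnc1 (6.77), Pear1 (6.64), Gm11074 (6.55) and Tulp2 (5.99), as log2 fold changes. Of these 8, Slco1a5, AF085738, Lrrc4, Tnnc1, Pear1 and Tulp2 overlap genes on the opposite strand (Iapp, Gnas, Snd1, Nisch, Insrr and Nucb1). Ccdc107 and Gm11074 have no such partner among the genes with deposited values, which does not mean that they lack an overlap. Both were left out of the fit without overlapping genes, either for an overlap with a gene that has no deposited values or for want of a match in the reference. Slco1a5 stood at a mean of 2.91 RPM at 8 weeks and 7268 RPM at 20 weeks, while the overlapping Iapp, the gene of islet amyloid polypeptide, stood at 7430 and 7030 RPM. Tnnc1 went from 0.724 to 190 RPM beside Nisch at 168 and 189 RPM. Of 288 genes that rose by over 2 log2 units, 270 had a match in the reference and 247 of these (91.5%) overlapped an opposite-strand gene, against 45.6% of the other matched genes. Without genes that overlap an opposite-strand gene, an alternative chosen after the data were seen, 1384 were higher and 495 lower among 7011 tested. With scaling as well 1393 were higher and 2431 lower, with 825 and 1443 in wild type and 1081 and 1634 in knockout-labelled libraries. The scaling factors came from all tested genes, those that rose beside an opposite-strand gene included. That most calls were then lower therefore rests in part on those factors. The same factors gave the scaled list counts below, so falls there rest in part on them too.

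**Figure D4:**
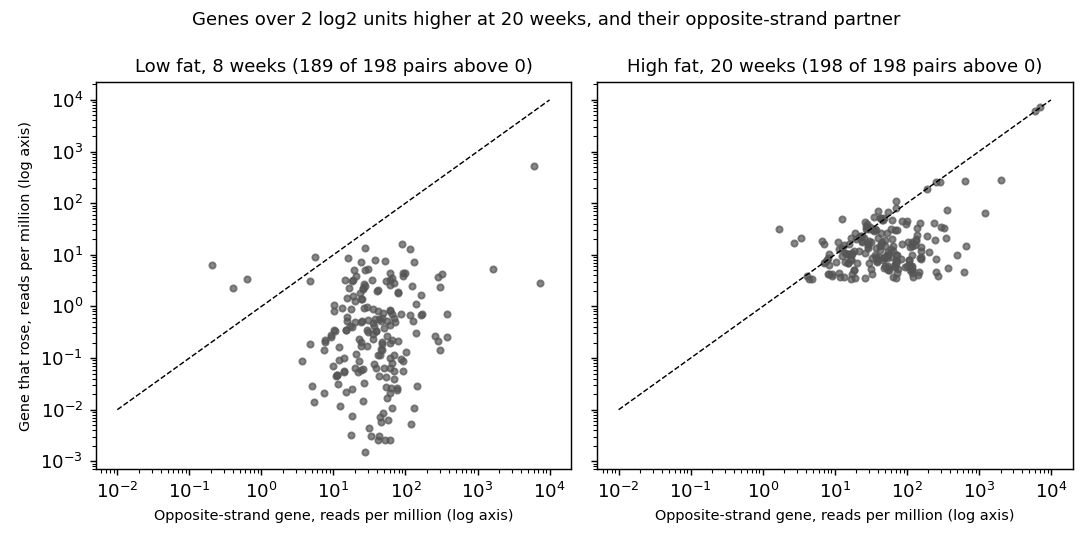
Mean RPM of 198 genes that rose by over 2 log2 units (y axes, log scale) against the mean of their opposite-strand partner (x axes, log scale), at 8 weeks (left) and 20 weeks (right). Points are gene pairs with both values above 0 and the dashed line marks equal values; the median gene stood at 0.798% of its partner at 8 weeks and at 32.1% at 20 weeks.

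In the endocrine lists falls were as many as rises or more. Of 11 alpha cell genes 0 rose and 6 fell (after scaling 0 and 6; 0 and 6 of 9), among them Irx1 (-0.95), Irx2 (-0.68) and glucagon (Gcg, -0.99). Of delta, PP and epsilon cell genes 1 rose and 3 fell of 7 (after scaling 1 and 5; 0 and 5 of 6), with Pyy at -1.11, Ppy at -1.05 and Ghrl, the ghrelin gene, at 0.84. Of beta cell genes 3 rose and 3 fell of 28 (after scaling 3 and 11; 1 and 7 of 16), including Ffar1 (-0.68) and Chgb (-0.86), while Ins1 (-0.30), Ins2 (-0.26) and Pdx1 (-0.35) did not pass. Of 20 cell cycle genes 1 rose and 13 fell (after scaling 1 and 14; 1 and 10 of 13). Of fibroblast, stellate and mural genes 0 rose and 7 fell of 11 (after scaling 0 and 8; 0 and 8 of 9), with Col6a3 at -1.22 and Thy1 at -0.87. The camera adjusted p was 7.0e-04 for alpha, 0.019 for delta, 0.02 for beta, 6.1e-10 for cell cycle and 1.6e-05 for fibroblast genes. With an estimated correlation these lists had an adjusted p of 0.75, 0.83, 0.94, 0.75 and 0.75.

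Other cell types gave small counts. Of acinar genes 6 rose and 0 fell of 28 (after scaling 0 and 0; 0 and 0 of 23), with Sycn (1.13), Spink3 (1.41) and Prss1 (1.38) as deposited, and trypsinogen genes such as Prss1 share reads with close copies. Of duct genes 2 rose and 2 fell of 9 (after scaling 2 and 3; 1 and 1 of 6), with Krt19 at -0.80 and Krt7 at -0.52. Of endothelial genes 1 rose and 1 fell of 13 (after scaling 1 and 6; 1 and 3 of 10), with Tie1 at -0.54 and Flt1 at 0.57, while Pecam1 (-0.53) did not pass as deposited. Of macrophage and antigen presentation genes 1 rose and 2 fell of 12 (after scaling 1 and 7; 0 and 6 of 10), with Fcer1g at -0.61, Cx3cr1 at -0.50 and Csf1r at 0.56, of which Csf1r and Cx3cr1 overlap opposite-strand genes. Of T and B lymphocyte genes 2 rose and 3 fell of 5 (after scaling 1 and 3; 1 and 1 of 3), with Ms4a1 at -0.70, Cd79b at -0.62 and Cd5 at 1.22. No gene of 3 Schwann cell and glia genes was called, nor the 1 tested adipocyte gene. Camera gave an adjusted p of 0.031 for endothelial and 0.0032 for macrophage genes (adjusted p of 0.94 and 0.75 with an estimated correlation).

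The lists of oxidative phosphorylation, ribosomal proteins and cholesterol synthesis held more falls than rises. Of oxidative phosphorylation genes 3 rose and 10 fell of 30 (after scaling 2 and 21; 1 and 13 of 17), with Uqcrq at -0.71 and Atp5o at 1.22. Of ribosomal protein genes 1 rose and 8 fell of 29 (after scaling 0 and 18; 0 and 10 of 19), with Rps14 at -0.56, Rpl27 at -0.51 and Rpl10a at -0.45, of which Rps14 overlaps Ndst1 on the other strand. Of cholesterol synthesis genes 0 rose and 1 fell of 22 (after scaling 0 and 13; 0 and 10 of 16), with Mvd at -0.38, while Srebf2 (0.42) and Fdps (-0.28) did not pass as deposited. By camera these 3 lists had an adjusted p of 2.2e-05, 1.1e-04 and 0.005, against an adjusted p of 0.75, 0.75 and 0.94 with an estimated correlation.

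The remaining lists did not pass camera. Of p53 target and senescence genes 6 rose and 0 fell of 17 (after scaling 6 and 5; 5 and 4 of 14), with the cell cycle inhibitor Cdkn1a at 0.95, Trp53inp1 at 1.08 and Zmat3 at 0.86. Of Wnt and TCF target genes 6 rose and 3 fell of 15 (after scaling 5 and 5; 3 and 3 of 7), with Tcf7l2 at 1.49 ± 0.21 (limma adjusted p = 2.5e-05), Lef1 at 2.34 ± 0.19 and Tcf7l1 at 1.05. Of incretin and cAMP signalling genes 6 rose and 0 fell of 17 (after scaling 4 and 1; 1 and 0 of 6), with Pde4d at 1.24, Adcy8 at 0.62 and Irs2 at 0.67. Gipr (0.07), Glp1r (0.15), Axin2 (0.12) and Trp53 (0.17) did not pass and turned negative with median-of-ratios scaling. Of apoptosis and survival genes 5 rose and 0 fell of 20 (after scaling 5 and 5; 1 and 3 of 11), with Bid at 0.90, Bcl2 at 0.77 and Casp9 at 5.30. On the other strand Casp9 overlaps the abundant acinar gene Cela2a, Bid overlaps Bcl2l13 (24.2 and 27.0 RPM beside 1.73 and 4.08 RPM of Bid at 8 and 20 weeks), and Ddit3, Tcf7l1 and Me1 overlap Mars, Gm15401 and A330041J22Rik. Of endoplasmic reticulum stress genes 7 rose and 1 fell of 25 (after scaling 7 and 7; 4 and 6 of 16), with Atf3 at 1.09, Ddit3 at 0.88 and Sdf2l1 at -0.72. Of immediate early and isolation stress genes 5 rose and 0 fell of 16 (after scaling 4 and 0; 3 and 0 of 11), with Hspa1a at 1.38, Hspa1b at 1.16 and Nr4a2 at 0.81. Of interferon response genes 3 rose and 1 fell of 13 (after scaling 3 and 3; 2 and 1 of 9), with Oas2 at 1.12, Ifit1 at 0.72 and Mx1 at 0.71. Of fatty acid and lipid genes 7 rose and 1 fell of 20 (after scaling 7 and 5; 2 and 3 of 11), with Me1 at 0.85 and Cpt1a at 0.70. Of disallowed and dedifferentiation genes 4 rose and 4 fell of 13 (after scaling 4 and 6; 4 and 4 of 9), with Aldh1a3 at 1.48, Serpina7 at 0.87 and Myc at 0.72. Of metallothionein and oxidative defence genes 4 rose and 3 fell of 16 (after scaling 3 and 8; 2 and 4 of 10), with Mt2 at 1.18 and Mt1 at 0.86. Further rises left out of the fit without overlapping genes were those of Lef1, Cdkn1a, Bcl2, Pde4d, Adcy8, Irs2, Atf3, Hspa1a, Oas2 and Mt2. In the lists above Atp5o, Ghrl and Sycn were left out too. The reason was an overlap with an opposite-strand gene that has no deposited values or the want of a match in the reference. Age, diet and any difference in how the libraries were made or counted at the 2 settings cannot be told apart in this comparison.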

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

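Tests of the floor of counts, of blood and of the library totals as denominator were chosen after the values they bear on had been seen; the other tests were set after the patterns were seen and before they were run. The genotype difference changed between settings for 9 genes by the limma interaction test. Its change, as a difference of log2 fold changes, was 3.23 for Aldh1a3, 2.75 for Bank1, 2.18 for Dock2, 1.81 for Arhgap15, 1.91 for Ptprc, 2.02 for Nos1, 1.39 for Ms4a1, 3.14 for Wdr95 and -3.56 for Erp27. It also changed for 5 gene lists by camera with the preset correlation, with medians of -0.25 for alpha cell, -2.62 for acinar, 1.17 for T and B lymphocyte, -0.23 for cholesterol synthesis and 0.11 for disallowed and dedifferentiation genes. None of the 5 passed with an estimated correlation, with adjusted p between 0.098 and 0.91.

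Of 26 genes called lower in the knockout-labelled libraries at 8 weeks 19 are known from leukocytes (a count made after the values were seen), while the T and B lymphocyte and macrophage lists had adjusted p of 0.055 and 0.59 by camera with an estimated correlation. The 19 genes had 161 or more reads in each wild-type library, not near a floor of counts (Ptprc 1024 and 1758 against 304 and 305, Bank1 1078 and 705 against 20 and 18). The tests of a floor could not decide on it. The filter fixed the outcome of the first, and in the second 6 of the 19 had 20 reads or fewer in a knockout-labelled library. In the third, taken up after these, the largest upper bound of the 95% counting interval of the ratio was 0.327. It took genes already called lower and covers counting error only, not the spread between libraries, so its outcome was all but fixed. Fewer B lymphocytes, by an effect of genotype or otherwise, may account for the lower values, as a hypothesis: over 18 measured genes of a second B lymphocyte list the median log2 ratio of RPM was -2.73 (quartiles -4.00 and -0.66) and 17 were lower, though its most abundant gene, Bach2, stood at 22.0 and 18.0 RPM in wild type against 7.58 and 16.5 RPM and how many of its genes islet cells express was not tested. Lymph node tissue in the wild-type islets met the bound written for it, with a median of -3.98 over 7 measured of 14 genes, but was left open because Cxcl13, Cr2, Ltb and Fcer2a, which is also in the B lymphocyte list, were lower and Enpp2 (130 and 115 against 101 and 168 RPM), Lyve1 and Chst4 were not. Blood met the bound written against it, with a median of -1.68 over 6 red cell genes (Hbb-b1 at 12.9 and 32.5 against 7.35 and 8.64 RPM), 1.05 above that of the B lymphocyte list, but was left open because that difference lies inside the spread of the list; for both, this demand on the spread was added after the values were seen.

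Aldh1a3 and Serpina7 were higher and Mafa lower in knockout-labelled libraries at 20 weeks, although of these only Aldh1a3 passed the threshold as deposited. Its limma adjusted p rose as high as 0.173 among the alternatives. The acinar content of the libraries was argued against, as the fold changes with the acinar list mean as covariate were at least 0.957 of those without it and Mafa then passed (-1.69, limma adjusted p = 0.0034), and so were reads of overlapping genes, as 0 of the 3 genes overlap a gene of like change. Median-of-ratios scaling could hardly change these fold changes. Its factors at 20 weeks were 1.17 and 1.02 in wild type and 1.01 and 1.11 in knockout-labelled libraries. The smallest ratio of 0.96 after this scaling was thus fixed beforehand and does not test the library totals as denominator. Mafa then had a limma adjusted p of 0.28 (-1.39 ± 0.32). A wider loss of mature beta cell genes with a gain of stress genes stays open: over 20 genes of a second list the median signed log2 fold change was 0.28 (quartiles 0.16 and 0.40), all 12 mature beta cell genes were negative and 6 of 8 stress genes positive, but 0 of them was called. All of the 12 but Glp1r and Sytl4 are also in the beta cell list fixed beforehand, so they are no independent set. In that list of 28 genes 21 were negative and 7 positive, Ins1 and Ins2 among the positive, with a median of -0.15. Its camera adjusted p was 0.064, and 0.85 with an estimated correlation. An effect of genotype on beta cell maturity may be behind such a loss, as a hypothesis.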

How the results depend on the processing

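edgeR on the recovered reads, the fit without genes that overlap an opposite-strand gene, and the latter with scaling were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because the labels give no replicate number shared between groups. Named genes gave 189 results: over all alternatives 2685 comparisons kept direction and side of the threshold, 207 kept direction and lost their call, 87 gained one and 33 changed sign. With 2 libraries per group, leaving 1 out assumes that the lone library varies like the other groups. Depth was 58.7 M reads or more, and the least of 19 called leukocyte genes had 161 reads in a wild-type library at 8 weeks. The cause was not tested for the changes below, except where fewer genes or libraries were used.

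Counts of called genes are given in the order 8-week genotype, 20-week genotype, mean genotype and interaction contrasts, against 28, 6, 14 and 9. Median-of-ratios scaling gave 9, 1, 2 and 3. edgeR on the recovered reads gave 24, 0, 2 and 3 (0 beside 1414 genes at an unadjusted p under 0.05). Without genes that overlap an opposite-strand gene 8, 2, 2 and 2 were called, with fewer genes tested. A minimum of 5 RPM gave 63 (49 higher), 23, 21 (12 higher) and 60 (18 positive), and no filter gave 1 at 20 weeks. At 20 weeks a pseudocount of 0.1, or no mean-variance trend, gave 2 higher and 2 lower. Without the mean-variance trend the mean and interaction contrasts gave 7 and 4. A fit of the compared libraries alone gave 266 at 20 weeks. A threshold of 0.10 gave 49, 10 and 26 for the first 3 contrasts. The acinar covariate gave 9, 19 and 2 for the 8-week, 20-week and interaction contrasts. Leaving out 1 library gave 16 to 224, 15 to 86, 14 to 131 and 6 to 139, and no called gene of these contrasts changed sign. At 8 weeks Arhgap15, Dock2, Ptprc, Aldh1a3, Bank1, Ms4a1, Wdfy4, Btla and Ikzf1 kept their call without each library, and 19 of the 28 genes lost it without knockout replicate 1.

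Between settings the count of 4971 was 7824 with median-of-ratios scaling, 7830 by edgeR and 1879 without overlapping genes, and 3462 to 6755 with 1 library left out. In wild type the count of 2476 was 5090 with scaling, 5059 by edgeR, 634 without overlapping genes, 4559 with the compared libraries alone, 1467 with the acinar covariate and 1103 to 4381 with 1 library left out. In knockout-labelled libraries the count of 2933 was 6015 with scaling, 6023 by edgeR, 889 without overlapping genes and 1464 to 5357 with 1 library left out.

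Camera with an estimated correlation called 0 lists in each of the 5 contrasts tested, against 8, 8, 13, 5 and 10 with the preset one. With 1 library left out the lists called numbered 5 to 13 at 8 weeks, 4 to 10 at 20 weeks, 9 to 13 for the mean, 5 to 10 for the interaction and 7 to 11 between settings, and 11 for the interaction with the acinar covariate. Tcf7 at 20 weeks (0.97) passed in the fit of the compared libraries alone, at 0.97, and in some fits with 1 library left out (0.65 to 1.30); at 8 weeks it stood at 0.13 to 0.25 and between settings at 1.003 to 1.324. Pearson's r of the 2 genotype contrasts was -0.041 with a minimum of 5 RPM and -0.070 to 0.101 with 1 library left out.

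The values that changed sign had not passed as reported. Between settings Gipr, Glp1r, Axin2 and Trp53 stood at -0.13, -0.054, -0.047 and -0.0099 with scaling and at -0.15, -0.079, -0.091 and -0.043 by edgeR, and Gipr and Trp53 at -0.13 and -0.0099 with scaling and without overlapping genes. With the acinar covariate Mafa at 8 weeks was 0.27 and Cdkn1a at 20 weeks -0.071. With 1 library left out the values ran, at 8 weeks, Glp1r -0.28 to 0.31, Tcf7l2 -0.52 to 0.56, Trp53 -0.10 to 0.29, Ins1 -0.10 to 0.011, Col3a1 -1.22 to 0.14, Mki67 -0.59 to 0.016, at 20 weeks, Gipr -0.45 to 0.055, Tcf7l2 -0.34 to 0.13, Trp53 -0.20 to 0.090, Gcg -0.55 to 0.34, Cdkn1a -0.30 to 0.32, Mki67 -0.92 to 0.52, and between settings Gipr -0.051 to 0.20.

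Splits of the 8 libraries into 4 and 4, in a model with the other factor as a term, numbered 34. For the setting 1 of 34, the real one, gave as many genes as the real 5238, and the highest other gave 0. This is the smallest share that 34 splits can give. The other splits each mix libraries of both settings, which differ widely, so low counts there were largely set by the design and chance is not excluded. For the mean genotype contrast the model with the other factor as a term called 0 genes (487 at an unadjusted p under 0.05). These were fewer than the 14 of the 4-group fit, and the cause was not tested. Each of the 34 splits gives at least 0, so the count says nothing on chance here. Of the other splits 5 called more, the highest 48 genes, which points to a structure of the samples. That split set wild-type replicate 1 of both ages and both 20-week knockout-labelled libraries against the rest, and what parts them was not tested.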

Other observations

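The tests of the library totals and of a block around Tcf7 were chosen after the results were seen, as was the list of neuron genes. That list was made after Prph, Nos1, Sncg and Nefl had been seen among the genes called at 8 weeks, and holds these 4, so it does not test them. Of 15 measured genes 12 were lower in knockout-labelled libraries, with a median log2 ratio of RPM of -1.69 (quartiles -1.90 and -0.17). Without the 4, 8 of 11 were lower, with a median of -0.51, and limma called none of those it tested. Vip, a neuropeptide of pancreatic nerves, stood at 7.44 and 8.05 RPM in wild type and 1.24 and 3.72 RPM in knockout-labelled libraries, and Prph, a neuronal filament gene, at 6.95 and 3.11 against 0.345 and 1.77 RPM. Stmn2 stood at 2.89 and 1.85 against 0.272 and 1.11 RPM and the receptor gene Chrna3 at 2.14 and 1.503 against 0.193 and 0.964 RPM. Nefm, Elavl4 and Th were not lower, with log2 ratios of 0.041, 0.051 and 0.34. Of a second T lymphocyte list 12 genes were measured, with a median of -0.73 at 8 weeks and 10 lower.

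At 20 weeks 288 genes rose by over 2 log2 units. Median-of-ratios scaling moved the median log2 fold change of all tested genes from 0.17 to -0.007, a shift far smaller than these rises. That 100% of these genes were still called higher after rescaling was therefore fixed beforehand and is no test of the library totals. A same-strand overlap was argued against, with an odds ratio of 0.962 (Fisher's exact test, 95% interval 0.713 to 1.28). An overlap with an opposite-strand gene had an odds ratio of 12.8 (95% interval 8.33 to 20.6), which fits the hypothesis that reads of both strands were counted in the 20-week libraries and not in the 8-week ones. Reads from introns may add to it: across 5588 genes with no overlapping gene, Spearman's rho of the fold change with the intron share was 0.42, and the median log2 fold change went from -0.18 in 234 genes with no intron to 0.50 in 331 genes with an intron share above 0.95. Age and diet changed together, and whether library making or counting did is not given, so a biological part of these rises stays open.

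Pttg1 lies on the chromosome of Tcf7, as does Dock2, and a block of another strain's chromosome carried with the deleted allele could lower such genes, as a hypothesis. Of the 50 genes with the smallest p for the mean genotype contrast, 3 lay within 20 Mb of Tcf7 (Pttg1, Dock2 and Lyrm7), against 317 of all matched genes tested, and Acsf2, on the same chromosome, lay outside. A block would be present at both ages, but Pttg1 stood at 2.93 RPM in wild type and 2.44 RPM in knockout-labelled libraries at 8 weeks and at 3.36 and 0.283 RPM at 20 weeks, and Dock2 at 8.85 and 1.60 RPM at 8 weeks and at 6.39 and 7.83 RPM at 20 weeks. Lyrm7 was at 1.79 and 0.681 RPM and at 1.78 and 0.859 RPM. The odds ratio was 2.59 (Fisher's exact test, p = 0.12, 95% interval 0.513 to 8.12), so for the 3 genes as a set a strain block and chance cannot be told apart. The change of Pttg1 between ages did not pass in the interaction test, and Lyrm7 was lower at both ages. Neither gene decides on a like effect at both ages. Dock2 cannot be read on this, as its values at 20 weeks may hold reads of Fam196b, which it overlaps on the other strand. Fam196b stood at 4.75 and 2.90 RPM in wild type and 5.84 and 6.12 RPM in knockout-labelled libraries at 20 weeks.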
